A study of Homo sapiens with 20 samples.

How the data were processed

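The data are RNA-seq counts per gene for 20 libraries, made from polyadenylated RNA of the cell lines DOHH2 and U2932 per the labels. Per the submitters' processing notes, the authors aligned the reads with STAR to GRCh38.p10, counted reads per gene with HTSeq and tested them with edgeR, without versions given for any of the tools. The deposited values are whole-number counts per gene, neither filtered nor normalised per the labels, for 58288 genes in each library, together with 5 summary counts of reads not assigned to a gene. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of a gene and its antisense partner could not be told apart. Gene symbols and coordinates were taken from GENCODE v29 (GRCh38), where 16433 of the genes tested had an entry, 15157 of them with the same versioned identifier.

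The libraries held 30363255 to 52275430 counts in genes, which sets the precision of genes with few counts. The summary counts came to 32.7 to 43.0% of all counts, those in genes included, in 19 libraries and to 62.7% in DOHH2 TK 18 h replicate 1. Of all counts, those outside any gene were 4.54 to 10.1%, ambiguous ones 1.49 to 2.82% and those without a unique alignment 20.7 to 56.6%. Whether a read with several alignments was counted once or once per alignment is not given. The genes with the most counts, 10 in each library, took 7.21 to 9.16% of the counts in genes and mitochondrial genes 3.29 to 8.08%. Levels are given as CPM, counts relative to the library's total, scaled by TMM factors, as mean ± SD of the libraries of a group, unless said otherwise. Where a group had no counts, a floor of 3 counts in its library served as the bound of a fold change.

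All 20 libraries were fitted together in R 4.3.3 with edgeR 4.0.16, with 1 coefficient for each of the 8 groups of line, compound and time, TMM scaling and robust quasi-likelihood dispersion. Genes were kept if at least 3 libraries reached the CPM that equals 10 counts in the median library (0.288 CPM), which left 16478 of 34160 genes with any count. Contrasts were tested with edgeR's quasi-likelihood F test and adjusted by Benjamini-Hochberg over the genes kept, with a threshold of 0.05. The contrasts were TK against DMSO in each line at each time, the difference of these between the lines and between the times, DMSO at 18 h against 8 h in each line, and DOHH2 against U2932 in DMSO at 8 h. Standard errors of log2 changes came from the fitted test statistic. Of 36 gene lists written down before the data were examined, 35 had members that could be tested. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation of 0.01, again with a correlation estimated per list, and with fry, and adjusted over the 35 lists. Members of a list were also adjusted over the list alone. Correlations of log2 changes were taken over 10457 genes with a mean log2 CPM of at least 2.

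The genes named are those of a rule set beforehand. For each TK contrast it takes up to 10 rises and 10 falls past the threshold with the largest changes, a mean of at least 5 CPM and all TK libraries on one side of all DMSO libraries, and for the other contrasts up to 5 of each. From each list it takes up to 4 members past the threshold, or else the member with the smallest p. Any gene outside the rule is said to be chosen after its values were seen. Single-gene results of some genes that the rule takes are left out of the text. The groups, contrasts, filter, thresholds and the first set of alternatives were also fixed before the data were examined.

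The alternatives were RLE scaling, no filter, a filter at 50 counts (12880 genes), the libraries of 1 line only, the replicate number as a block, the libraries of the 2 groups only, a test against a 1.5-fold change, the DMSO libraries of both times as control at 18 h, DESeq2 1.42.0, camera with an estimated correlation, fry, and each library left out in turn where its group held another. A fit without DOHH2 TK replicate 1 of both times and a fit with limma's voom and library quality weights were chosen after seeing the data. For the gene lists, RLE scaling, the block, the estimated correlation and fry were planned, and the other alternatives were added after seeing the data. Where 1 library was left in a group it was assumed to vary like the other groups. For contrasts of 3 against 3 libraries every other split of the 6 libraries was tested too.

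The fits were tested on simulated data with the means and sizes of the real libraries, 16478 genes and 200 changed genes per contrast. Of the 2-fold changes, 95% were recovered for TK in DOHH2 at 8 h, 91% in DOHH2 at 18 h, 89% in U2932 at 8 h and 65% in U2932 at 18 h, and of the 4-fold changes 100% in each. For the differences between lines 54% of the 2-fold changes were recovered at 8 h and 34% at 18 h, and for those between times 62% in DOHH2 and 30% in U2932. No simulated change was called in the wrong direction, and 4 to 13 unchanged genes were called per contrast. The simulated changes were placed only in genes above a set mean level, so the recovery of genes of low level was not tested. Noise was drawn independently for each gene, without deviations of whole libraries. The real libraries had such deviations, with quality weights from 0.137 (DOHH2 TK 18 h replicate 1) to 4.27 (U2932 DMSO 8 h replicate 2). The shares recovered may therefore overstate what the fits recover in the real data. No library was a copy of another of its group: Pearson's correlation of log2 CPM between libraries of a group was 0.983 to 0.994. No library was left out of the fit of all libraries.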

Results

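Polyadenylated RNA was sequenced from 2 human lymphoma cell lines, DOHH2 and U2932, after 8 h or 18 h with the compound labelled TK or with its solvent DMSO. At 8 h there were 3 DMSO and 3 TK libraries of DOHH2 and 3 DMSO and 2 TK libraries of U2932. At 18 h there were 2 DMSO (replicates 1 and 3) and 3 TK libraries of DOHH2, and 1 DMSO (replicate 2) and 3 TK libraries of U2932. The 20 libraries held 30363255 to 52275430 counts in genes (median 34671988), and 19717 to 24992 genes had at least 1 count. The labels do not say whether replicates were separate cultures, so the p-values measure a spread between libraries that may be technical. Every result for U2932 at 18 h rests on the single DMSO library of that time, which was assumed to vary like the other groups.

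Some libraries stood apart from their groups. In DOHH2 TK 18 h replicate 1, 56.6% of all counts were without a unique alignment, against 20.7 to 34.3% in the other 19 libraries. That library scored -63.3 on the second principal component of the DOHH2 libraries (19.4% of the variance), where the others scored -8.14 to 22.9. In DOHH2 TK 8 h replicate 1, mitochondrial genes took 3.29% of the counts, against 5.06 to 8.08% elsewhere, and its score on the first component (22% of the variance) was 49.2 against -29.4 to 22.4. Among the U2932 libraries, the first component (36.3% of the variance) held DMSO 8 h at 19.1 to 30.5 and TK 18 h at -35.5 to -28.2. TK 8 h replicate 1 of U2932 lay between them at -1.38, TK 8 h replicate 2 at 28.9, and the DMSO 18 h library at -12.8.

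The lines themselves differed widely in DMSO at 8 h (n = 3 each). Interferon-stimulated genes were mostly higher in DOHH2 (23 of 24 higher, 1 lower), as were plasma cell genes (10 of 14 higher, 2 lower), targets of MYC (19 of 25 higher, 1 lower) and targets of p53 (17 of 26 higher, 5 lower). Genes of cholesterol synthesis and uptake were mostly lower in DOHH2 (16 of 22 lower, 1 higher), and all 4 measured targets of the aryl hydrocarbon receptor were lower. Markers of germinal centre B cells were also mostly lower in DOHH2 (12 of 15 lower, 2 higher). BCL6, a repressor that marks germinal centre B cells, had a mean of 0.106 CPM in DOHH2 and 400 CPM in U2932, and MYBL1 had 0.658 and 66.6 CPM. GCSAM (163 and 51.7 CPM) went the other way. Markers of activated B cells were split, with 5 of 12 higher in DOHH2 and 4 lower. IRF4 was higher in DOHH2 (871 against 402 CPM), and PIM1 and FOXP1 were lower. DOHH2 is usually classed with the germinal centre type and U2932 with the activated type, which these markers do not follow. A check for mixed-up samples on genes linked to the donors, chosen after the data were seen, found 0 of 20 libraries that did not match the label of their line. The lines are named as labelled throughout, and the markers leave a doubt about their identity that the counts cannot fully settle.

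In all, 11177 of 16478 genes differed between the lines with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5432 higher and 5745 lower in DOHH2, and DESeq2 gave 11214. For the lists of genes named above, adjusting over the list alone gave the same numbers. GYPC was at 49.2 ± 9.80 CPM (SD) in DOHH2, BBOX1 at 35.7 ± 6.32 and CPS1 at 25.4 ± 7.61, and none of the 3 genes had a count in U2932. GUCA1A was at 65.1 ± 2.67 CPM and IGF2BP2 at 61.6 ± 7.70 in U2932, without a count in DOHH2, as were PYGO1 (51.9 ± 9.31), ALDH7A1 (43.2 ± 1.22) and ME1 (41.0 ± 5.61). HLA-DQB1 was at 226 ± 68.7 CPM in DOHH2 and 0.0395 CPM in U2932; HLA genes are polymorphic and share sequence, so these counts are uncertain. In limma's camera with its preset correlation, the 7 lists passed at adjusted p = 9.45e-10 for the interferon list to 0.0365 for the aryl hydrocarbon receptor list. With an estimated correlation none passed (adjusted p = 0.216 to 0.77). The cholesterol list lost its call without DOHH2 DMSO 8 h replicate 1 (median log2 difference -0.63 in place of -0.74, camera adjusted p = 0.0749), and so did the aryl hydrocarbon receptor list (-3.78 in place of -3.80, 0.0558).

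What TK did to DOHH2 after 8 h was small, with 3 lists past camera by the preset correlation only. Across 30 mitosis genes, 29 had a positive log2 change, with a median of 0.22. CCNB1, the cyclin that drives entry into mitosis, was at 205 ± 30.8 CPM with TK and 140 ± 14.5 with DMSO (n = 3 each), a log2 change of 0.55 (SE 0.15). Across 28 DNA replication genes, 26 had a negative change, with a median of -0.12, and UHRF1, a chromatin factor of replicating cells, had -0.47 (SE 0.14). Cholesterol genes had positive changes in 19 of 22 members (median 0.15), among them IDI1 at 0.31 (SE 0.14). Targets of p53 showed no shift as a list, with 17 of 26 positive (median 0.06, camera adjusted p = 0.32). In camera with its preset correlation, the mitosis (adjusted p = 8.07e-08), DNA replication (0.000265) and cholesterol (0.00608) lists passed. With an estimated correlation none of them did (adjusted p = 0.833 each).

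No single gene of DOHH2 passed edgeR's quasi-likelihood test at 8 h. In that test 497 genes had an unadjusted p under 0.05, where chance gives 824, and DESeq2 also called 0. Counts below 824, here and in other contrasts, mean that small p-values were rarer than chance gives. They do not show that TK had no effect. Whether a spread between libraries that the fit leaves out or correlation among genes caused this was not tested. Adjusted over the list alone, CCNB1 and PTTG1 (log2 change 0.74) rose among the 30 mitosis genes and no member of the other 2 lists passed; PTTG1 was chosen after its values were seen. The mitosis median was 0.12 without DMSO 8 h replicate 2 or without TK 8 h replicate 3 and 0.36 without TK 8 h replicate 2. The DNA replication list lost its call without DMSO 8 h replicate 1 (median -0.0075), TK 8 h replicate 2 (-0.030) or TK 8 h replicate 3 (-0.091), and its median was -0.26 without DMSO 8 h replicate 2 and -0.31 without TK 8 h replicate 1. The cholesterol list lost its call without DMSO 8 h replicate 1 (0.044), TK 8 h replicate 2 (0.13) or TK 8 h replicate 3 (0.080).

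After 18 h in DOHH2, TK raised 11 genes and lowered 1, with targets of p53 at the front. MDM2, the ubiquitin ligase that p53 induces and that degrades p53, rose from 194 ± 16.6 to 438 ± 50.7 CPM (SD, n = 2 DMSO and 3 TK), a log2 change of 1.17 (SE 0.15). SESN1, a stress-induced sestrin, rose from 12.4 ± 0.338 to 27.8 ± 0.964 CPM, a log2 change of 1.16 (SE 0.15). All 26 measured p53 targets had positive log2 changes, with a median of 0.67. MDM2 and SESN1 passed over all genes; adjusted over the list alone, 16 rose, 0 fell and 10 did not pass. Those 16 included BBC3, a pro-apoptotic member of the BCL2 family (29.6 ± 10 against 12.1 ± 0.932 CPM), SESN2 (59.0 ± 21.5 against 28.3 ± 0.553 CPM) and the cell cycle inhibitor CDKN1A (log2 change 0.96, chosen after its values were seen). The p53 list passed camera with the preset correlation (adjusted p = 2.31e-22), with an estimated correlation (3.78e-05) and with fry (9.83e-07). MIR34AHG, the host transcript of the p53-induced microRNA miR-34a, rose by a log2 change of 1.09 (SE 0.20) and the receptor gene EDA2R by 1.08 (SE 0.19).

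The steepest rises in DOHH2 at 18 h were in genes of low level. H1F0, a linker histone of cells that leave the cycle, rose from 1.12 ± 0.361 to 23.2 ± 18.3 CPM (44.2, 10.5 and 15.1 in TK replicates 1, 2 and 3), a log2 change of 4.39 (SE 0.52) or 21-fold, and of 3.52 without TK 18 h replicate 1. CYP4F3, a fatty acid hydroxylase, rose from 0.557 ± 0.399 to 6.99 ± 2.47 CPM, a log2 change of 3.59 (SE 0.42), or 12.1-fold. That change was 3.05 without DMSO 18 h replicate 1, 4.65 without replicate 3 and 2.81 with the DMSO libraries of both times as control; its family holds similar genes, so its counts are uncertain. The histone gene HIST2H2BE rose 4.07-fold and HIST1H2BJ, chosen after its values were seen, 2.89-fold. Histone genes are near copies of each other and most of their transcripts lack a poly(A) tail, so their counts are uncertain. NEAT1, the RNA scaffold of paraspeckles, rose from 190 ± 17.6 to 325 ± 38.4 CPM (1.71-fold), MIR3142HG rose 1.91-fold and PNRC1 1.67-fold. TMEM238 fell from 6.32 ± 0.335 to 2.12 ± 0.225 CPM (n = 2 and 3), a log2 change of -1.57 (SE 0.26).

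**Figure D1:**
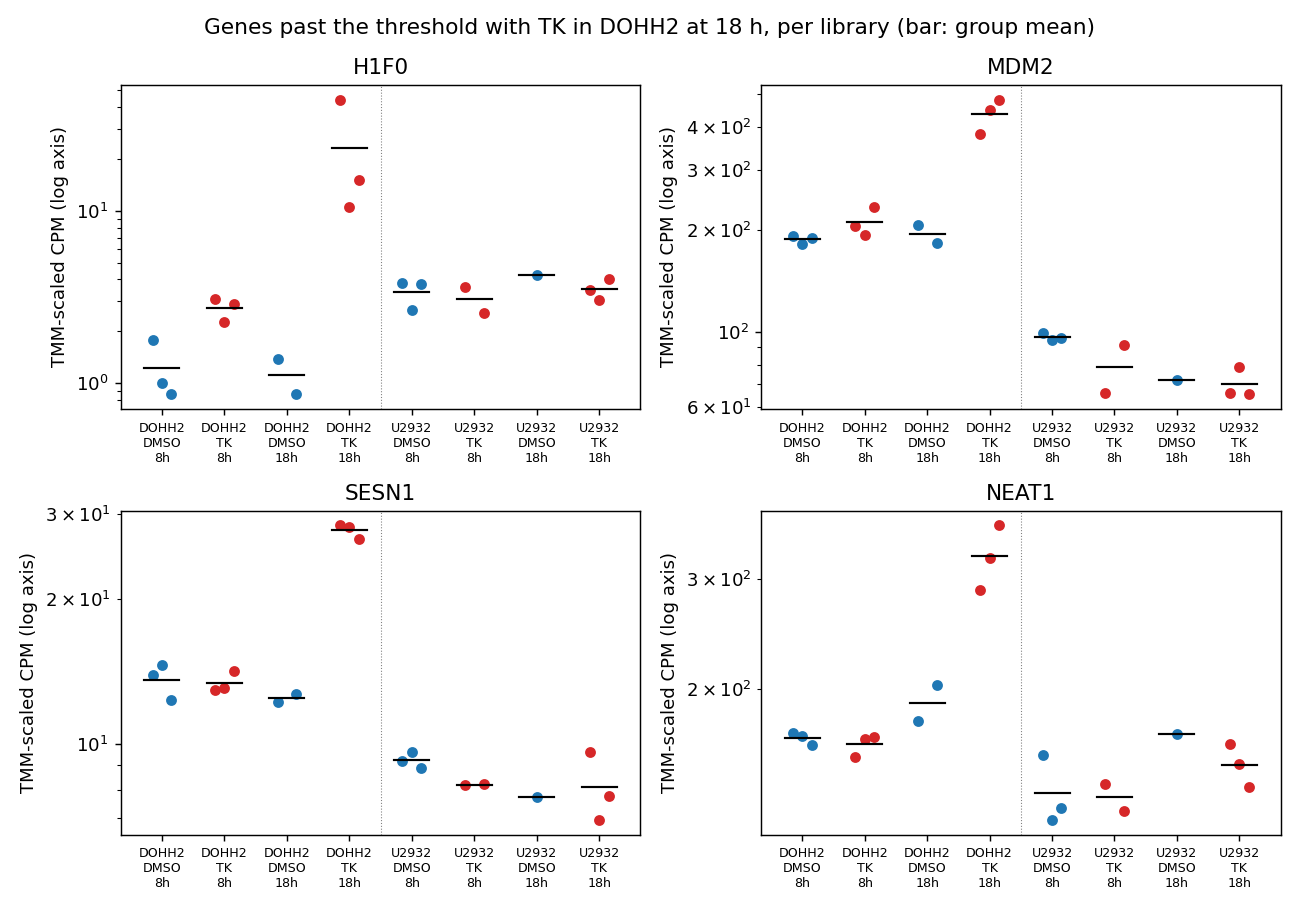
TMM-scaled CPM (log axis) of H1F0, MDM2, SESN1 and NEAT1 in each library, with DMSO in blue, TK in red and a bar at each group's mean. In DOHH2 at 18 h the MDM2 bar is at 194 CPM with DMSO and at 438 CPM with TK.

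The 12 genes had adjusted p-values of 0.000641 to 0.0403 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MDM2 lies on chromosome 12 at 68808176 to 68850686, SESN1 on chromosome 6 at 108986437 to 109094819, H1F0 on chromosome 22 at 37805093 to 37807436 and CYP4F3 on chromosome 19 at 15640897 to 15662825 (GRCh38, GENCODE v29). An unadjusted p under 0.05 was seen for 1411 genes (824 by chance), 741 higher and 670 lower, and DESeq2 called 90 genes, all 12 among them. With library quality weights 790 genes were higher and 1184 lower, so the balance of rises and falls depended on the fit. The libraries of DOHH2 alone gave 6 genes (H1F0, CYP4F3, MDM2, SESN1, MIR34AHG and TMEM238), those of the 2 groups alone 0, and a test against a 1.5-fold change 2, H1F0 and CYP4F3. Without DMSO 18 h replicate 1 of DOHH2 the count fell to 2 and without replicate 3 to 1, with the call lost for MDM2 without replicate 3 (log2 change 1.09), for H1F0 without replicate 3 (4.08), for CYP4F3 without replicate 1 (3.05) and for SESN1 without replicate 1 (1.13) or 3 (1.19). The count was 18 without TK 18 h replicate 1 and 8 without TK 18 h replicate 2. MIR34AHG, EDA2R, NEAT1 and PNRC1 also lost their calls without any 1 of TK 18 h replicates 2 and 3 and DMSO 18 h replicates 1 and 3. Their log2 changes without those libraries were 0.98 to 1.21, 1.01 to 1.08, 0.68 to 0.87 and 0.67 to 0.82. MIR3142HG and TMEM238 did so without TK 18 h replicate 2 (0.86 and -1.59), DMSO 18 h replicate 1 (0.93 and -1.52) or DMSO 18 h replicate 3 (0.95 and -1.63), and HIST2H2BE without either DMSO 18 h library (2.19 without replicate 1 and 1.87 without replicate 3). With the DMSO libraries of both times as control MIR3142HG was at 0.47.

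Other lists moved in DOHH2 at 18 h only by the preset correlation. All 28 DNA replication genes had negative log2 changes (median -0.31), and UHRF1 (-0.61, SE 0.16) and MCM4 (-0.47, chosen after its values were seen) fell when adjusted over the list alone. Mitosis genes had negative changes in 29 of 30 members (median -0.27), with none past either adjustment; UBE2C had -0.68 (SE 0.21). All 10 histone genes had positive changes (median 0.78), with 1 past over all genes and 5 adjusted over the list alone. All 17 NF-kB targets had positive changes (median 0.52), with 4 past adjusted over the list alone; CFLAR, an inhibitor of caspase 8, was at 133 ± 20.4 CPM against 93.0 ± 0.935. Immediate early genes had positive changes in 15 of 18 members (median 0.63), and ATF3, a stress-induced transcription factor, and JUN rose when adjusted over the list alone (0.96 and 1.16, JUN chosen after its values were seen). The camera adjusted p-values with the preset and with an estimated correlation were 6.21e-11 and 0.359 for DNA replication, 7.53e-06 and 0.501 for mitosis, and 6.88e-07 and 0.198 for histones. They were 1.12e-06 and 0.384 for NF-kB and 0.000104 and 0.359 for immediate early genes. Without TK 18 h replicate 1 the histone median was 0.40 and the NF-kB median 0.28, and without DMSO 18 h replicate 1 the immediate early median was 0.40. With the DMSO libraries of both times as control the NF-kB median turned to -0.21 without a call, the DNA replication median was -0.13, and the calls of mitosis (-0.085) and immediate early genes (0.070) ended.

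In DOHH2 at 18 h, 9 further lists moved by the preset correlation only (camera adjusted p = 0.000118 for DNA repair to 0.0173 for activated B cell markers, and 0.359 to 0.501 with an estimated correlation). DNA repair (-0.33, 17 of 19 negative, FANCA at -0.44), oxidative phosphorylation (-0.15, 20 of 20 negative) and glycolysis and hypoxia (-0.19, 18 of 24 negative) were lower. Tubulins were lower by their median (-0.38, 6 of 10 negative), and TUBA1B was at 860 ± 2.95 CPM against 1370 ± 52.3. B cell receptor signalling (0.16, 20 of 20 positive), B cell identity (0.17, 14 of 18), activated B cell markers (0.17, 11 of 12, PIM2 at 0.69), the BCL2 family (0.27, 12 of 16) and autophagy and lysosome genes (0.096, 16 of 22, GABARAPL1 at 0.92) were higher. Adjusted over the list alone, 4 tubulins and FANCA fell, and BBC3, PMAIP1, PIM2, GABARAPL1 and MAP1LC3B rose; PMAIP1 and MAP1LC3B were chosen after their values were seen. Without TK 18 h replicate 1 the calls ended for oxidative phosphorylation (median -0.11), B cell receptor signalling (0.11), B cell identity (0.14), activated B cell markers (0.089), the BCL2 family (0.18) and autophagy (0.057), and glycolysis moved to -0.29. Without DMSO 18 h replicate 1 they ended for tubulins (-0.17), B cell identity (0.093) and glycolysis (-0.11). Without DMSO 18 h replicate 3 they ended for activated B cell markers (0.10), the BCL2 family (0.18) and autophagy (0.075), and B cell identity moved to 0.26. Without TK 18 h replicate 2 tubulins (-0.32) and glycolysis (-0.15) lost theirs, and without replicate 3 tubulins did (-0.31) and oxidative phosphorylation moved to -0.24. With the DMSO libraries of both times as control only oxidative phosphorylation kept its call. The other medians were -0.090 for DNA repair, -0.099 for glycolysis, -0.26 for tubulins, 0.093 for B cell receptor signalling, 0.075 for B cell identity, 0.070 for activated B cell markers, 0.14 for the BCL2 family and 0.081 for autophagy (camera adjusted p = 0.0533 to 0.639).

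In U2932 after 8 h with TK, 2 lists passed camera, by the preset correlation only. Mitosis genes had positive log2 changes in 29 of 30 members, with a median of 0.30. CCNB1 was at 246 ± 63.5 CPM with TK (n = 2) and 166 ± 25.2 with DMSO (n = 3), a log2 change of 0.57 (SE 0.16). All 10 tubulins had positive changes (median 0.33), with TUBA1B at 0.41 (SE 0.19). Targets of p53 had positive changes in 10 of 26 members (median -0.036, camera adjusted p = 0.376). Both the mitosis (adjusted p = 1.02e-12) and tubulin (0.00537) lists passed camera with the preset correlation and neither did with an estimated correlation (0.915 each). No gene of U2932 passed edgeR's quasi-likelihood test at 8 h and none adjusted over either list alone; 276 had an unadjusted p under 0.05 (824 by chance), and DESeq2 called 0. Both calls ended without TK 8 h replicate 1, where the mitosis median was 0.059 and the tubulin median -0.015. That fit leaves 1 TK library, so whether this library is the source stays open. Without TK 8 h replicate 2 the medians were 0.54 and 0.59, without DMSO 8 h replicate 1 the mitosis median was 0.54, and without DMSO 8 h replicate 2 the tubulin list lost its call (0.25).

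In U2932 after 18 h, the 3 TK libraries could be set against 1 DMSO library only, which was assumed to vary like the other groups. In camera, with the preset correlation only, they had higher levels of mitosis, cholesterol and heat shock genes and lower levels of DNA replication genes than that library. The TK libraries also differed from all other U2932 libraries in fewer reads outside any gene (5.87 to 6.36% against 7.78 to 10.1%), a larger share of ribosomal protein genes (11.7 to 12% against 8.26 to 10.1% of counts) and lower TMM factors (0.945 to 0.983 against 1.04 to 1.09). Mitosis genes had positive changes in 26 of 30 members (median 0.46), with CCNB1 at 380 ± 20.2 CPM against 164 (log2 change 1.21, SE 0.23). Cholesterol genes had positive changes in 21 of 22 members (median 0.52), with HSD17B7, an enzyme of the pathway, at 35.0 ± 2.68 CPM against 19.8. All 14 heat shock genes had positive changes (median 0.48), with the chaperone HSPA8 at 3470 ± 313 CPM against 2100. All 28 DNA replication genes had negative changes (median -0.34), with cyclin CCNE2 at 12.3 ± 1.75 CPM against 31.4. Adjusted over the list alone, 9 mitosis, 4 cholesterol and 5 heat shock genes rose and 6 DNA replication genes fell. All 4 targets of the aryl hydrocarbon receptor (median 0.75, AHRR at 1.17), 17 of 20 oxidative phosphorylation genes (0.21, UQCRFS1 at 0.42) and 18 of 25 MYC targets (0.15, LYAR at 0.61) had positive changes, with AHRR alone past when adjusted over its list. Targets of p53 had positive changes in 15 of 26 members (median 0.071, camera adjusted p = 0.655).

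The camera adjusted p-values of these 7 lists of U2932 at 18 h, with the preset and with an estimated correlation, were 9.89e-11 and 0.665 for mitosis, 9.89e-11 and 0.108 for cholesterol, and 6.13e-10 and 0.108 for heat shock. They were 4.5e-09 and 0.665 for DNA replication, 0.00368 and 0.108 for the aryl hydrocarbon receptor, 0.00262 and 0.854 for oxidative phosphorylation, and 0.0216 and 0.854 for MYC targets. With fry, heat shock and the aryl hydrocarbon receptor passed (adjusted p = 0.0219 each). With the DMSO libraries of both times as control the cholesterol median turned to -0.030, the calls of DNA replication (-0.14) and the aryl hydrocarbon receptor (0.39) ended, and oxidative phosphorylation moved to 0.44 and MYC targets to 0.23, so the calls of cholesterol, DNA replication and the aryl hydrocarbon receptor depended on that 1 library as control. Without TK 18 h replicate 2 the MYC list lost its call (0.15, camera adjusted p = 0.161).

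**Figure D2:**
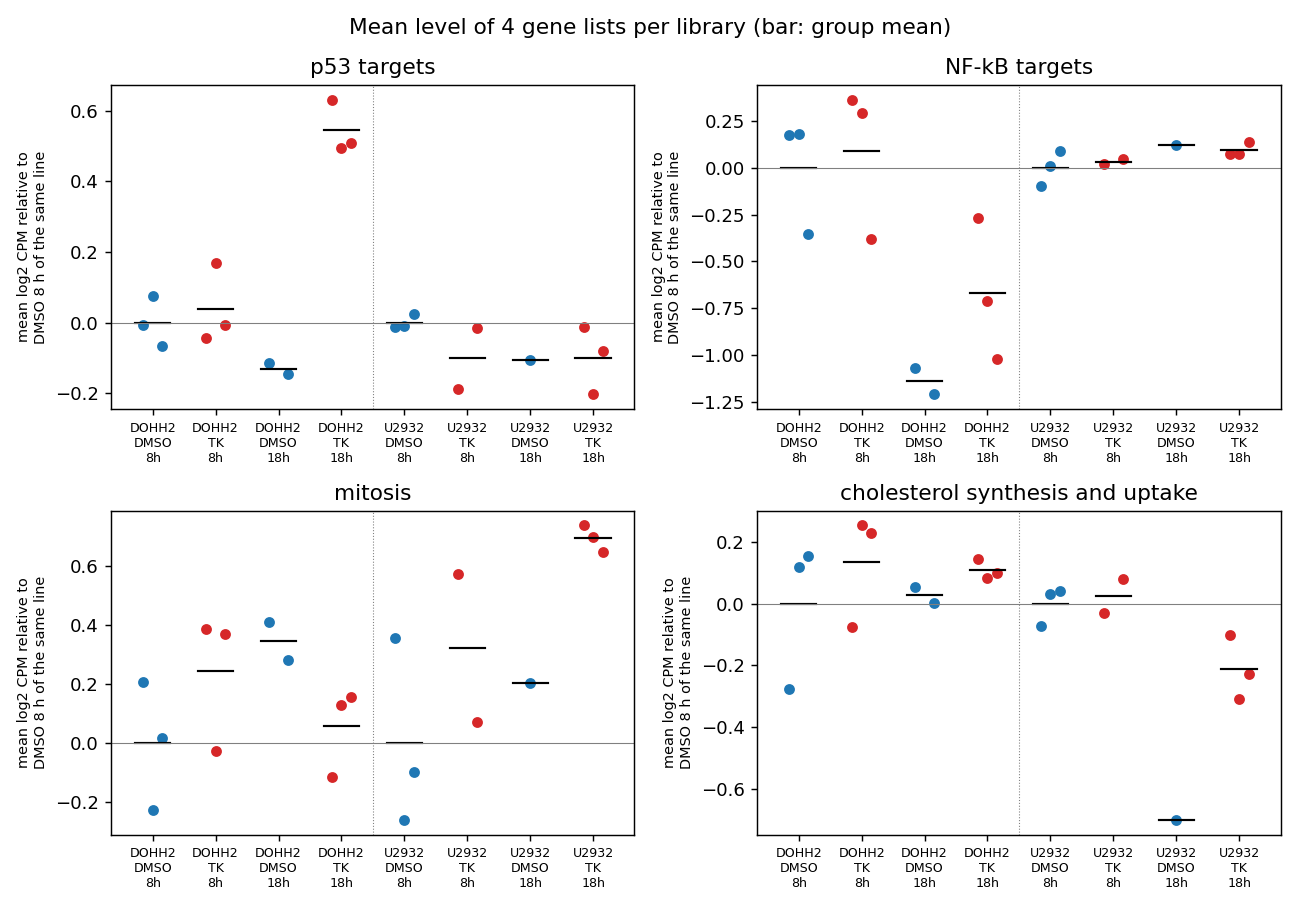
Mean log2 CPM of the p53, NF-kB, mitosis and cholesterol lists in each library, relative to the DMSO 8 h libraries of the same line, with DMSO in blue and TK in red. The median log2 change of the p53 list with TK at 18 h was 0.67 in DOHH2 and 0.071 in U2932.

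In the fit of all libraries, only 3 single genes separated TK from DMSO in U2932 at 18 h, and each set the lone DMSO library apart. IGKV3-20, a kappa light chain variable gene on chromosome 2 at 89142574 to 89143160 (GRCh38, GENCODE v29), had 0 counts in the DMSO library and a mean of 657 CPM, before TMM scaling, in the 3 TK libraries. Against a floor of 3 counts (0.0606 CPM) in the DMSO library, it was at least 10800-fold higher with TK (edgeR's quasi-likelihood test, adjusted p = 2.21e-06). The floor covers counting error only, and kappa V genes share sequence, so reads can be lost to several places. INSR, the insulin receptor, had 35 counts with DMSO and 3, 0 and 5 with TK, a log2 change of -3.15 (SE 0.52, adjusted p = 0.0371 in edgeR's quasi-likelihood test). PIGR, the receptor that carries polymeric immunoglobulin, had 132 counts against 7, 11 and 6; it was chosen after its values were seen. The 8 h DMSO libraries of U2932 resembled the TK libraries in these genes, with IGKV3-20 at 621 ± 28.6 CPM and INSR at 0.143 ± 0.0319. With the DMSO libraries of both times as control IGKV3-20 had a log2 change of 0.55 and INSR -2.04, and neither passed. INSR also lost its call without TK 18 h replicate 1 (-3.36), 2 (-2.61) or 3 (-3.75), and the count was 4, 1 and 1 without them. Over 13 alternatives INSR kept its call in 4, with log2 changes of -7.66 to -2.04. An unadjusted p under 0.05 was seen for 1227 genes (824 by chance), and DESeq2 called 60, 2 of the 3 among them. The number depended on the fit: with the DMSO libraries of both times as control, most of them of 8 h, it was 1654, with 0 of the 3 among them.

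Against the DMSO libraries of 18 h, of which U2932 had 1, the response of p53 targets to TK differed between the lines. The difference, DOHH2 minus U2932, was positive for 23 of 26 members with a median of 0.66, and 6 of them passed adjusted over the list alone and none over all genes. MDM2 had a difference of 1.21 (SE 0.23). The list passed camera with the preset correlation (adjusted p = 1.36e-10), with an estimated correlation (0.00182) and with fry (0.000312). With the 8 h DMSO libraries of each line as control, a test chosen after the data were seen, the median difference was 0.53 and the list did not pass camera with an estimated correlation (adjusted p = 0.0925). Mitosis genes differed the other way in all 30 members (median -0.71, 13 past adjusted over the list alone, CCNB1 at -1.30). That list had a camera adjusted p = 7.91e-18, and 0.26 with an estimated correlation.

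Among single genes, H1F0 (4.65, SE 0.69, adjusted p = 0.0127), INSR (3.30, SE 0.56, 0.0335), IGKV3-20 (0.00648) and PIGR (0.0335, chosen after its values were seen) differed in their response at 18 h between the lines in edgeR's quasi-likelihood test. The last 3 are the genes in which the lone DMSO library of U2932 stood apart. An unadjusted p under 0.05 was seen for 1017 genes (824 by chance), and DESeq2 called 23. H1F0 lost its call without DOHH2 DMSO 18 h replicate 1 (5.01) or 3 (4.34) or U2932 TK 18 h replicate 2 (4.55), and kept it at 3.79 without DOHH2 TK 18 h replicate 1. The call of IGKV3-20 ended without DOHH2 DMSO 18 h replicate 1 (adjusted p = 1 in edgeR's test). INSR lost it without either DOHH2 DMSO 18 h library (3.28 and 3.33) or any 1 of the U2932 TK 18 h libraries (3.51, 2.76 and 3.90).

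Another 11 lists differed between the lines at 18 h by the preset correlation in camera (adjusted p = 2.97e-07 to 0.0398), and none of them with an estimated correlation (adjusted p = 0.174 to 0.47). Higher in DOHH2 were the responses of histones (median difference 1.25), NF-kB targets (0.61), immediate early genes (0.40) and interferon-stimulated genes (0.32). Lower were oxidative phosphorylation (-0.40), heat shock (-0.42), cholesterol (-0.46), tubulins (-0.51), aryl hydrocarbon receptor targets (-0.62), MYC targets (-0.14) and glycolysis and hypoxia (-0.21). Relative to 8 h DMSO of the same line, NF-kB targets at TK 18 h lay lower in DOHH2 than in U2932. Their mean log2 CPM was -0.27, -0.713 and -1.02 against 0.0735, 0.0771 and 0.138. Cholesterol genes lay higher (0.145, 0.0843 and 0.101 against -0.102, -0.311 and -0.227), so both differences turned with the control. Glycolysis turned as well, with overlap between the lines, and the group means of the other lists kept their direction. Adjusted over the list alone, 4 histone genes and 1 heat shock gene passed and no member of the other 9 lists. Without DOHH2 TK 18 h replicate 1 the histone median was 0.43 and NF-kB 0.40, MYC targets moved to -0.22, and the calls of immediate early genes (0.27) and the aryl hydrocarbon receptor (-0.44) ended. Without DOHH2 DMSO 18 h replicate 1 tubulins (-0.38) and glycolysis (-0.14) lost theirs and the interferon median was 0.60, and without replicate 3 the interferon call ended (0.17) and MYC targets moved to -0.092. Without DOHH2 TK 18 h replicate 2 glycolysis (-0.14) and MYC targets (-0.15) lost theirs and the aryl hydrocarbon receptor moved to -1.17. Glycolysis also lost its call without DOHH2 TK 18 h replicate 3 (-0.19) and U2932 TK 18 h replicates 2 (-0.22) and 3 (-0.22), and MYC targets without U2932 TK 18 h replicate 2 (-0.14), with a move to -0.21 without replicate 3.

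At 8 h the difference between the lines reached 2 lists and no gene. All 10 tubulins had a lower response in DOHH2 (median difference -0.40, TUBA1B at -0.69) and FOXO targets a higher one (14 of 16 positive, median 0.21, IRS2 at 3.07 with an SE of 1.2), with none past when adjusted over either list alone. The camera adjusted p-values were 0.00267 and 0.0233, and 0.891 for both with an estimated correlation. edgeR's quasi-likelihood test called 0 genes, 316 had an unadjusted p under 0.05 (824 by chance), and DESeq2 called 0. The tubulin call ended without DOHH2 DMSO 8 h replicate 1 (-0.28), DOHH2 TK 8 h replicate 3 (-0.23) or U2932 TK 8 h replicate 1 (-0.12), and the median was -0.66 without DOHH2 TK 8 h replicate 1 or U2932 TK 8 h replicate 2. The FOXO call ended without DOHH2 DMSO 8 h replicate 1 (0.16), DOHH2 TK 8 h replicate 3 (0.11), U2932 DMSO 8 h replicate 1 (0.12) or U2932 TK 8 h replicate 2 (0.24), and the median was 0.34 without DOHH2 DMSO 8 h replicate 2.

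Between 8 h and 18 h, the response of DOHH2 to TK grew for p53 targets. All 26 members had a larger change at 18 h (median difference 0.67), with SESN1 past over all genes and 8 past adjusted over the list alone. The list passed camera with the preset (adjusted p = 1.26e-16) and an estimated correlation (0.000177). A small part of that difference lay in the DMSO libraries, which moved the opposite way. Relative to 8 h DMSO, the mean log2 CPM of the list was -0.116 and -0.147 in DMSO at 18 h. With TK at 18 h it was 0.631, 0.495 and 0.508. SESN1 (1.18, SE 0.19) and CYP4F3 (3.62, SE 0.53) were the 2 genes past edgeR's quasi-likelihood test (adjusted p = 0.0408 each), and neither passed with the libraries of DOHH2 alone; 712 had an unadjusted p under 0.05 (824 by chance), and DESeq2 called 7. SESN1 lost its call without any 1 of the 11 DOHH2 libraries (1.13 to 1.25), and CYP4F3 without any but DMSO 18 h replicate 3 and TK 18 h replicate 2 (3.07 to 3.78), with 4.67 without DMSO 18 h replicate 3. In U2932 the p53 list had a median difference of 0.15 (16 of 26 positive, camera adjusted p = 0.284).

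A further 9 lists of DOHH2 differed between the times by the preset correlation (camera adjusted p = 3.11e-14 to 0.0447), and none with an estimated correlation (0.249 to 0.747). All 30 mitosis genes had a lower response at 18 h (median difference -0.50, CENPA at -0.79). Histones (0.79), immediate early genes (0.51), NF-kB targets (0.41) and interferon-stimulated genes (0.23) had higher responses, and glycolysis (-0.26), oxidative phosphorylation (-0.22), DNA repair (-0.23) and DNA replication (-0.17) lower ones. The DMSO libraries moved the opposite way with time in immediate early, NF-kB, mitosis, glycolysis, DNA repair and DNA replication genes. Relative to 8 h DMSO, the mean log2 CPM of the DMSO 18 h libraries was -1.07 and -1.21 for NF-kB targets. It was 0.411 and 0.28 for mitosis and 0.382 and 0.0238 for interferon-stimulated genes, which moved with their difference. The differences of the lists that moved the opposite way in DMSO cannot be assigned to TK alone. Adjusted over the list alone, 1 histone gene passed, HIST2H2BE at 1.92 (SE 0.46), and no member of the other 8 lists. Without TK 18 h replicate 1 the histone median was 0.35 and the DNA replication median -0.27, and the calls of NF-kB targets (0.13), interferon-stimulated genes (0.13) and DNA repair (-0.10) ended. Without TK 8 h replicate 1 the calls of oxidative phosphorylation (-0.10), DNA replication (-0.0094) and DNA repair (-0.16) ended. Without TK 8 h replicate 3 those of NF-kB targets (0.19), interferon-stimulated genes (0.18) and DNA repair (-0.089) did. Without DMSO 8 h replicate 2 those of DNA replication (-0.094), interferon-stimulated genes (0.11) and DNA repair (-0.068) ended, and NF-kB targets moved to 0.26 and immediate early genes to 0.32. The interferon call also ended without DMSO 8 h replicate 1 (0.21) and DMSO 18 h replicate 3 (0.052), and its median was 0.35 without DMSO 18 h replicate 1 or TK 18 h replicate 3. DNA repair lost its call without DMSO 8 h replicate 3 (-0.18), DMSO 18 h replicate 1 (-0.17) and replicate 3 (-0.21), and DNA replication without TK 18 h replicate 2 (-0.13). Without TK 8 h replicate 2 the medians of DNA replication (-0.28), DNA repair (-0.39) and immediate early genes (0.80) were larger, as were those of DNA replication (-0.32) and DNA repair (-0.41) without DMSO 8 h replicate 1.

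In U2932, where the response at 18 h was taken against 1 DMSO library, 6 lists differed between the times by the preset correlation only. Cholesterol (21 of 22 positive, median difference 0.41), heat shock (0.37), aryl hydrocarbon receptor (0.86) and mitosis genes (0.18) had a higher response at 18 h than at 8 h, and DNA replication (-0.37) and DNA repair genes (-0.28) a lower one. That DMSO library itself differed from those of 8 h in cholesterol (median -0.68) and DNA replication genes (0.33), so these 2 differences cannot be assigned to TK. Relative to the 8 h DMSO libraries, its mean log2 CPM was -0.439 for aryl hydrocarbon receptor targets and -0.181 for heat shock genes, outside their range. It was 0.159 for DNA repair and 0.202 for mitosis genes, within that range. The differences of these other lists rest on the same library and cannot be assigned to TK alone. IDI1 had a difference of 0.88 (SE 0.26) and HSPA8 of 0.61 (SE 0.21), with no member of the 6 lists past when adjusted over the list alone. The camera adjusted p-values were 2.41e-08, 8.51e-07, 0.00508, 0.0351, 7.23e-07 and 0.0351 in that order, and 0.156 to 0.912 with an estimated correlation. IGKV3-20 was the only gene past edgeR's quasi-likelihood test (adjusted p = 5.01e-06), from its 0 counts in the DMSO 18 h library; 512 had an unadjusted p under 0.05 (824 by chance), and DESeq2 called 1. The mitosis median turned to -0.032 without DMSO 8 h replicate 1 and to -0.012 without TK 8 h replicate 2. It was 0.28 without DMSO 8 h replicate 2 or 3 and 0.46 without TK 8 h replicate 1, and its call ended without TK 18 h replicate 1 (0.13) or 2 (0.22). DNA repair lost its call without any of the libraries left out in turn but DMSO 8 h replicate 1 and TK 18 h replicate 1 (-0.28 to -0.18).

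Across 10457 genes, the log2 changes with TK of DOHH2 and U2932 had Pearson's r = 0.061 and Spearman's rho = 0.17 at 8 h and 0.037 and 0.13 at 18 h. Between 8 h and 18 h they had 0.096 and 0.23 in DOHH2 and 0.24 and 0.27 in U2932. These are correlations across genes, which are not independent replicates, and the 4 comparisons share no library. At an unadjusted p under 0.05, 121 genes were lower with TK in both lines at 18 h (31.1 for independent lists) and 44 higher (20.8). At 8 h the numbers were 7 (2.31) and 11 (1.85).

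The DMSO libraries of DOHH2 themselves changed between 8 h (n = 3) and 18 h (n = 2), with 24 genes higher and 80 lower at 18 h. Of 17 targets of NF-kB, 12 fell over all genes and 14 adjusted over the list alone (median -1.20). BCL2A1, an anti-apoptotic BCL2 family member, fell from 27.3 ± 7.55 to 6.78 ± 0.944 CPM, the cytokine subunit EBI3 from 30.6 ± 6.91 to 8.90 ± 0.488 and TNFAIP2 from 792 ± 185 to 281 ± 34.0. Of 16 cytokines and homing receptors, 2 fell over all genes and 5 adjusted over the list alone (median -1.15), and of 18 immediate early genes 1 and 8 (median -0.61, CCL4 at -1.93). With an estimated correlation none of these 3 lists passed camera (adjusted p = 0.123 for NF-kB targets and for cytokines, and 0.329 for immediate early genes). Of 24 glycolysis and hypoxia genes, 7 rose when adjusted over the list alone and 3 over all genes. These were PFKFB4 (from 7.99 ± 2.35 to 21.5 ± 6.51 CPM), BNIP3L (log2 change 1.12) and KDM3A (0.68). KLF2, a transcription factor of resting lymphocytes, rose from 10.2 ± 3.28 to 25.9 ± 1.14 CPM and STS, the steroid sulfatase gene, from 25.0 ± 4.92 to 55.5 ± 2.71. PHF7 rose (log2 change 1.25), and ACHE (-2.04), IL32 (-1.86) and CD82 (-1.67) fell. Of the germinal centre markers MME and MYBL1 rose and SERPINA9 fell, and of the p53 targets FAS fell (-0.79, SE 0.16). The sum of epithelial and stromal markers, before TMM scaling, was lower too. It was 25.6, 18.1 and 13.0 CPM at 8 h and 9.24 and 7.09 CPM at 18 h, and COL1A1 led it (mean 12.4 CPM in DOHH2). The list as a whole showed no common fall. Its mean log2 CPM, relative to 8 h DMSO, was 0.253, 0.114 and -0.367 at 8 h and 0.64 and -0.542 at 18 h.

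The 5 rises and 5 falls that the rule set beforehand took by size had adjusted p-values of 0.00406 to 0.0265 in edgeR's quasi-likelihood test; 1786 genes had an unadjusted p under 0.05 (824 by chance), and DESeq2 called 280. Without either DOHH2 DMSO 18 h library the count was 0 (1 library against 3), with the log2 change of BCL2A1 at -2.16 without replicate 1 and -1.87 without replicate 3, KLF2 at 1.39 and 1.30, and PFKFB4 at 1.08 and 1.71. The count was 43 with the libraries of DOHH2 alone, where PFKFB4, PHF7 and CD82 lost their calls, 138 without DMSO 8 h replicate 1 and 11 without DMSO 8 h replicate 2, where PFKFB4 (1.28), KLF2 (1.27), PHF7 (1.15), BNIP3L (0.99), IL32 (-1.76), EBI3 (-1.58) and CD82 (-1.47) lost their calls. Without DMSO 8 h replicate 3 PFKFB4 (1.35) and PHF7 (1.16) lost theirs. The NF-kB (camera adjusted p = 8.36e-22), cytokine (1.45e-06), immediate early (2.57e-05) and glycolysis (5.08e-05) lists passed with the preset correlation, and none with an estimated correlation (0.168 for glycolysis). With fry, NF-kB (adjusted p = 0.00735), glycolysis (0.0234) and cytokines (0.0259) passed. Higher at 18 h by the preset correlation were also mitosis (30 of 30 positive, median 0.35), DNA replication (28 of 28, 0.34), DNA repair (19 of 19, 0.43) and the unfolded protein response (15 of 19, 0.18). Lower were B cell identity (-0.21), B cell receptor signalling (-0.13), MHC class II (-0.45), MYC targets (-0.11) and p53 targets (-0.13). Adjusted over the list alone, 3 DNA replication genes rose and 6 B cell identity genes, 3 of B cell receptor signalling, 1 of MHC class II and 1 p53 target fell, and no member of the other 4 lists passed. These 9 lists had camera adjusted p-values of 3.84e-08 to 0.0452 with the preset correlation and of 0.378 to 0.652 with an estimated one. With DMSO 8 h replicate 1 left out the calls of MHC class II (-0.081), p53 targets (-0.10) and the unfolded protein response (0.16) ended, and DNA repair moved to 0.66, B cell receptor signalling to -0.24 and MYC targets to -0.18. With DMSO 8 h replicate 2 left out those of B cell identity (-0.095), B cell receptor signalling (-0.080), p53 targets (-0.099) and the unfolded protein response (0.13) ended. With DMSO 8 h replicate 3 left out that of MYC targets did (-0.080) and B cell identity moved to -0.36. Without DMSO 18 h replicate 1 those of B cell receptor signalling (-0.096) and MYC targets (-0.12) ended and B cell identity moved to -0.12. Without DMSO 18 h replicate 3 those of MHC class II (-0.34), p53 targets (-0.13), the unfolded protein response (0.18) and MYC targets (-0.12) ended and B cell identity moved to -0.36.

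In U2932 the 1 DMSO library of 18 h, the one that stands apart in IGKV3-20, PIGR and INSR, was set against 3 of 8 h, which describes that library and does not separate it from a change with time. Cholesterol genes were lower in it in 20 of 22 members (median -0.68), and 16 fell when adjusted over the list alone. IDI1, an isomerase of the pathway, was at 151 CPM in it against 287 ± 6.16, MZB1, a chaperone of antibody-secreting cells, at 76.6 against 31.3 ± 0.512, and the mitochondrial carrier UCP2 at 476 against 221 ± 8.39. ABCA7 (1.13) and PRKCB (0.84) were higher as well. IGKV3-20 was at least 10900-fold lower, against the floor of 3 counts, and PIGR, chosen after its values were seen, was higher. These 6 genes had adjusted p-values of 2.49e-06 to 0.0437 in edgeR's quasi-likelihood test; 1873 had an unadjusted p under 0.05 (824 by chance), and DESeq2 called 148. MZB1, UCP2, ABCA7 and PRKCB each lost their calls without any 1 of the 3 DMSO 8 h libraries, with log2 changes of 1.27 to 1.33, 1.08 to 1.17, 1.1 to 1.2 and 0.79 to 0.94.

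The cholesterol list passed camera with the preset correlation (adjusted p = 1.34e-12), not with an estimated one (0.183), and passed fry (0.0211). Another 10 lists of the U2932 DMSO libraries passed with the preset correlation alone, with camera adjusted p-values of 0.000115 to 0.0484, and of 0.28 to 0.756 with an estimated correlation. Higher in the 18 h library were DNA replication (median 0.33), oxidative phosphorylation (0.23), the unfolded protein response (0.24, 7 of 19 past adjusted over the list alone, MANF at 0.91), interferon-stimulated genes (0.29), tubulins (0.44), plasma cell genes (0.21), B cell identity (0.24), mitosis (0.17) and epithelial and stromal markers (1.31, from low levels: DCN at 1.53 against 0.294 CPM). Metallothioneins and zinc export genes were lower (-0.69, SLC30A1 at -1.34). Without DMSO 8 h replicate 1 the calls of B cell identity (0.19) and plasma cell genes (0.11) ended and mitosis moved to 0.36. Without DMSO 8 h replicate 2 those of tubulins (0.38) and mitosis (0.080) ended and plasma cell genes moved to 0.32. Without DMSO 8 h replicate 3 those of mitosis (0.12), metallothioneins (-0.55) and epithelial and stromal markers (1.09) ended.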

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

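All tests of explanations in this part, other than the splits, were chosen only after the result was seen.

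A test of the difference itself set 4 genes and 13 lists apart between the lines at 18 h and 2 lists at 8 h. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the genes were IGKV3-20 (adjusted p = 0.00648), H1F0 (0.0127), INSR (0.0335) and PIGR (0.0335). By limma's camera with the preset correlation the lists at 18 h were mitosis (adjusted p = 7.91e-18), p53 targets (1.36e-10), oxidative phosphorylation (2.97e-07), heat shock (3.52e-07), cholesterol (4.29e-06), histones (6.63e-06), NF-kB targets (0.000936), interferon-stimulated genes (0.00186), tubulins (0.00423), immediate early genes (0.01), MYC targets (0.0109), aryl hydrocarbon receptor targets (0.0158) and glycolysis and hypoxia (0.0398). At 8 h they were tubulins (0.00267) and FOXO targets (0.0233). Only the p53 list at 18 h passed with an estimated correlation.

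The same kind of test set the response at 18 h apart from that at 8 h. In DOHH2 the genes were SESN1 and CYP4F3 (adjusted p = 0.0408 each in edgeR's quasi-likelihood test). The lists in camera were p53 targets (1.26e-16), mitosis (3.11e-14), histones (4.33e-05), glycolysis and hypoxia (8.48e-05), oxidative phosphorylation (0.000147), NF-kB targets (0.000639), immediate early genes (0.000893), DNA replication (0.00145), interferon-stimulated genes (0.0298) and DNA repair (0.0447), and of these only p53 targets passed with an estimated correlation (camera adjusted p = 0.249 to 0.747 for the other 9). In U2932 the gene was IGKV3-20 (5.01e-06 in edgeR's test). The lists in camera were cholesterol (2.41e-08), DNA replication (7.23e-07), heat shock (8.51e-07), aryl hydrocarbon receptor targets (0.00508), mitosis (0.0351) and DNA repair (0.0351), and none passed with an estimated correlation (camera adjusted p = 0.156 to 0.912). Among reads not assigned to a gene, which the comparisons do not use, 2 TK libraries of DOHH2 lay above every DMSO library. Of all counts, TK 8 h replicate 1 had 2.82% as ambiguous (2.8% in the next library) and TK 18 h replicate 1 had 56.6% without a unique alignment (34.3% in the next).

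The rise of p53 targets in DOHH2 at 18 h was weighed against technical causes. Without TK 18 h replicate 1 the list still passed camera with an estimated correlation (adjusted p = 0.000776, median 0.64), which argues against that library as the whole cause. Against the 8 h DMSO libraries it passed too (0.00121, median 0.52), which argues against a drift of the 18 h DMSO libraries. The difference between the lines (0.00182 in camera with an estimated correlation) tests no cause of it, and with the 8 h DMSO libraries of each line as control it did not pass (0.0925, median 0.53), so whether it rests on the lone U2932 DMSO 18 h library stays open. A response to TK that differs between the lines and an unrecorded difference between cultures or library batches, which the labels do not give, both stay open.

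The lone U2932 DMSO 18 h library differed from the other U2932 libraries in IGKV3-20, PIGR and INSR. Across 64 genes specific to DOHH2 its median level was 0.362% of that in DOHH2 (5th to 95th percentile 0.137 to 1.13%, highest other U2932 library 0.171%), which argues against a library of the other line or a mixture with over 5% of it. INSR, at 0.603% of its DOHH2 level, goes with traces of DOHH2 reads, and PIGR, at 2080%, argues against them for that gene. The other kappa V genes summed to 0.771 CPM above the highest other U2932 library (13.8 against 13.0 CPM) while IGKC was at 1850 CPM (1330 to 1960 across U2932), which argues against another known kappa V gene taking the place of IGKV3-20. Reads of a changed V gene lost in alignment or counting and a different subline of U2932 were not tested and stay open.

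Mitosis genes passed camera with TK at 8 h in both lines with the preset correlation only (adjusted p = 0.833 in DOHH2 and 0.915 in U2932 with an estimated one), so tests of it with the preset one decide nothing. In U2932 the call ended without TK 8 h replicate 1 (camera adjusted p = 0.429, median 0.059), and in DOHH2 the highest adjusted p with any 1 of the 6 libraries left out was 0.018 (medians 0.12 to 0.36), so a single library as the source stays open in both. By replicate number, each TK 8 h library lay above the DMSO library in the list's mean log2 CPM, relative to 8 h DMSO. DOHH2 replicates 1, 2 and 3 had 0.385, -0.0249 and 0.371 with TK and 0.208, -0.226 and 0.018 with DMSO. U2932 replicates 1 and 2 had 0.573 and 0.0714 with TK and 0.357 and -0.26 with DMSO. If the numbers mark pairs, which is not known, this argues against a single library as the whole source in either line. A difference in cell cycle stage between cultures that has nothing to do with TK stays open. The 10 splits of the 6 DOHH2 libraries are too few for a share under 0.05: the real split gave 3 lists and another 15, with 7 of 10 at least as large; whether this comes from a structure of the samples or from correlation within the lists (0.626 for mitosis) was not tested.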

How the results depend on the processing

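The fits without DOHH2 TK replicate 1 of both times and with library quality weights were chosen after the data were seen, and so were all list tests other than those with RLE scaling, the block, an estimated correlation or fry; the other alternatives were planned. Under the alternatives to 177 single-gene results, 2269 values kept their side of the threshold, 155 lost the call and 96 gained it. None changed sign with a call in either fit, and changes of sign without a call were not counted. Under those to 89 list results, 992 values kept direction and side of the threshold, 321 lost the call and 6 changed sign. RLE scaling moved no count of genes or lists by over 1.5 times. Gene counts are in the order given and, unless stated, the cause of a change was not tested.

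Without a filter the counts for TK were 32 (DOHH2 8 h), 170 (DOHH2 18 h), 9 (U2932 8 h) and 102 (U2932 18 h), for the difference between lines 18 (8 h) and 73 (18 h), between times 58 (DOHH2) and 16 (U2932), and for DMSO over time 445 and 332; the lists came to 1 for the lines at 8 h, 7 for U2932 DMSO and 12 for the line background. The stricter filter gave 1 gene for U2932 18 h, 2 for the lines at 18 h, 1 for the times in DOHH2 and 6 lists for the lines at 8 h. The libraries of 1 line alone gave 6 (DOHH2 18 h), 0 (times), 43 (DMSO), 5 (U2932 18 h), 2 (times) and 94 (DMSO). The 2 groups alone gave 0 in DOHH2 and 179 in U2932 at 18 h, and the test against a 1.5-fold change 2 and 1. DMSO of both times as control gave 62 (11 of the 12 among them) and 9 lists in DOHH2 at 18 h and 1654 (823 higher, 831 lower, 0 of the 3 among them) in U2932. With it the NF-kB median was -0.21 in DOHH2 and the cholesterol median -0.030 in U2932, since the 18 h DMSO libraries were lower in both.

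DESeq2 gave 90 and 60 at 18 h, 23 between lines, 7 between times in DOHH2, and 280 and 148 for DMSO. Of the lists, 1 passed with an estimated correlation for DOHH2 18 h, the lines at 18 h and the times in DOHH2 (p53 targets each time), and 0 in the other 8 contrasts; fry gave 1 in these 3, 2 for U2932 18 h, 3 and 1 for DMSO, 24 for the line background and 0 elsewhere. Without both DOHH2 TK replicates 1 the counts were 76 (DOHH2 18 h, the 12 among them), 12 (lines 18 h), 0 (times) and 303 (DMSO), with 7 lists for DOHH2 8 h and 7 for the lines at 8 h. Quality weights, lowest at 0.137 for DOHH2 TK 18 h replicate 1, gave 1974 (790 higher, 1184 lower) and 236 at 18 h, 117 (lines 18 h), 7 and 0 (times), and 1837 and 1513 (DMSO), with 9 lists for DOHH2 8 h, 9 for the lines at 8 h and 7 for U2932 DMSO, and a DNA repair median of -0.0029 between times in DOHH2.

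With 1 library left out, the counts ranged over 1 to 18 for DOHH2 18 h, 1 to 4 for U2932 18 h, 0 to 5 for the lines at 18 h, 0 to 2 for the times in DOHH2, 0 to 138 for DOHH2 DMSO and 1 to 2 for U2932 DMSO. The lists ranged over 2 to 10 for DOHH2 8 h, 9 to 16 for DOHH2 18 h, 0 to 3 for U2932 8 h and 0 to 7 for the lines at 8 h. The tubulin median of U2932 8 h ranged from -0.015 to 0.59, and the mitosis difference between times in U2932 from -0.032 to 0.46. With the replicate number as a block the count for the lines at 18 h was 2 (both among the 4), DOHH2 18 h had 11 (6 of the 12 among them), U2932 18 h 2 (1 of the 3) and the times in DOHH2 3 (0 of the 2, SESN1 and CYP4F3), and no other count of genes or lists moved by over 1.5 times. INSR moved with the block to a log2 change of -7.66 in U2932 at 18 h and a difference of 7.86 between the lines, both without a call. Of 7 same-numbered pairs 3 deviated together, with a correlation over 0.1 (-0.097 to 0.64 over the 7), and 4 did not. Where a group held 2 libraries their deviations mirror each other, so such pairs say little. In DOHH2 at 8 h replicates 1, 2 and 3 had 0.30, 0.64 and -0.097. There TK replicate 1 with DMSO replicate 2 had -0.43, and TK replicate 2 with DMSO replicate 1 had -0.55. The numbers were not taken as pairs. The list counts of the splits there went with the numbers as well, so a tie by number in DOHH2 at 8 h stays open. Depth limits the genes near the floor of 3 counts, such as INSR and PIGR in U2932.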

Other observations

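The tests of splits in this part were planned and the choice of markers of other cells was made before the data were examined. Markers of T and NK, myeloid and erythroid cells were low in every library, and single epithelial and stromal markers were not. Summed over the list, T and NK cell markers came to 5.10 to 9.43 CPM (TRBC2 highest in DOHH2, TRAC in U2932), myeloid markers to 0.0967 to 2.59 CPM and erythroid markers to 0 to 0.219 CPM. Epithelial and stromal markers came to 7.09 to 31.9 CPM in DOHH2 (13.0 to 25.6 CPM in the DMSO libraries of 8 h, 7.09 and 9.24 CPM in those of 18 h), where COL1A1 led with a mean of 12.4 CPM, and to 22.7 to 36.9 CPM in U2932, where EPCAM led with 27.4 CPM.

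For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For TK in DOHH2 at 8 h the real split called 0 genes and the highest of the others 0, so 10 of 10 were as large. For DOHH2 against U2932 in DMSO at 8 h the real split called 11177 genes and the highest of the others 0, so 1 of 10 was as large. For gene lists between the lines the real split gave 7 and the highest of the others 11, with 6 of 10 as large. Some splits between the lines thus gave more lists than the real one, without any gene.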
